A study of Mus musculus with 9 samples.

How the data were processed

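Messenger RNA of whole kidney tissue from mice was sequenced in 9 libraries, 3 in each of 3 groups. Per the labels' protocols, mice were started at 6 weeks of age on a high-fat diet with 49% of calories from fat or on a control diet (NCD) with 11.32%. The high-fat group also received 2 injections of the beta-cell toxin streptozotocin (STZ) at 30 mg/kg, on days 60 and 63 of the diet, and blood glucose was tested on day 65. One of the diabetic groups was then dosed by mouth with dehydrozingerone (DHZ), a ginger-derived curcumin analogue, at 50 mg/kg for 2 weeks. The groups are called NCD vehicle, HFD-STZ vehicle and HFD-STZ DHZ. They were taken from the sample titles, since the labels' treatment field names the compound for all 9 libraries. The labels give every library a batch date of its own that follows the order of the groups, so batch and group cannot be told apart. The labels speak of 9 kidney tissue samples and do not say that each came from a separate animal, so the p-values measure only the spread between these samples. Sex and strain are not given in the sources used here.

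The deposited table holds raw counts per gene, as whole numbers, for 55359 Ensembl genes, and it holds 0 other columns of per-sample values. Per the labels' protocols, the libraries were made with a stranded kit after capture of polyadenylated RNA. Per the submitters' processing notes, FastQC, Trim Galore and STAR were used, with the mouse build GRCm39 (mm39). Their versions, the counting program, its strand and multiple-mapping settings and the annotation release are not given in the sources used here. Reads that a gene shares with a near-identical copy, an overlapping gene or an antisense partner can therefore not be separated, and values of such genes are uncertain. The reference at hand was of an older build, so no coordinates are printed and it served only for gene class, length, GC content and which genes lie inside others. Gene symbols were matched on the Ensembl identifier for 94.1% of the genes in the table and 99.5% of the genes tested.

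Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, which left 17179, and library sizes were scaled by the trimmed mean of M values (TMM). All 9 libraries entered 1 quasi-likelihood fit with group as the only term, which left 6 residual degrees of freedom and a common dispersion of 0.0893. Each of the 3 comparisons used the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p below 0.05. Every adjusted p of a gene in the text comes from this test unless another is named, all tests are two-sided, and standard errors (SE) of log2 fold changes were derived from the F statistic. Library sizes are given in M counts, where M is the prefix mega. CPM are counts per M counts of TMM-scaled library size, except that those of Xist and the Y-linked genes, the check for sex, are per M of the total count. Groups are given as mean ± SD with n = 3.

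Gene lists for cell types, pathways and foreign tissues were written from textbook knowledge, 49 in all, of which 45 had at least 4 tested genes. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and called at an adjusted p below 0.05. Camera compares a list with all other genes. Camera with a correlation estimated for each list, and fry, which asks whether a list's genes move on balance one way, were run beside it. Members were also counted with their p-values adjusted over the list alone. The model and treatment comparisons share the HFD-STZ vehicle libraries. Data without any effect, and with the same spread in all groups, were therefore simulated 50 times to give the values that sharing would then produce.

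Genes named for the comparisons follow a rule. Outside it stand some genes that describe the libraries, such as Gm28661 and Malat1, and some under the other observations, such as Havcr1 and Cyp27b1. In each comparison the rule takes the 10 called genes that rose most and the 10 that fell most, with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out names that are only gene-model numbers. It adds up to 4 members with the lowest p from each called list and from the lists for podocytes, fibrosis and matrix, tubular injury, glomerular basement membrane and junctions, inflammatory cytokines and NF-kB, and the NRF2 antioxidant response. It also adds up to 10 genes called in opposite directions by the model and the treatment, and the sex chromosome check genes. Some genes that meet the rule are left out of the text because they are withheld for evaluation. The groups, lists, tests, naming rule and alternatives were fixed before the data were examined, except for 5 alternatives and the tests of explanations, which the closing section names.

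Total counts per library were 15.1 to 47.5 M. A count of 0 allows up to 3 counts in that library, a limit that covers counting error only. The procedure was tested on simulated counts for the real genes with 200 genes changed. Of 4-fold changes it recovered 92%, 86% and 95% in the model comparison, the treatment comparison and the comparison of HFD-STZ DHZ with NCD vehicle (16511, 16375 and 16475 genes tested), and of 2-fold changes 18%, 20% and 14%. False calls made up 7.56%, 6.19% and 4.39% of all calls there. Alternatives were other scalings (relative log expression as in DESeq2, library size only), no filter or a stricter one, and only the 2 groups compared. Others were the replicate number as a block, mitochondrial genes left out, DESeq2 1.42.0, limma-voom, and each library left out in turn. Statements that the call of a named gene or list held or was lost without a library cover the 6 libraries of the 2 groups compared. Libraries of the third group share the fit, so leaving them out can change calls too.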

Results

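Gene expression was measured by RNA sequencing of whole kidney in 9 libraries. There were 3 from control mice (NCD vehicle), 3 from mice made diabetic by a high-fat diet and streptozotocin (HFD-STZ vehicle), and 3 from diabetic mice given dehydrozingerone (HFD-STZ DHZ). Total counts per library in that order of groups were 25.9, 17.1 and 24.0 M (mega), 15.1, 22.7 and 34.9 M, and 27.6, 47.5 and 27.6 M. Mitochondrially encoded genes took 44.0% ± 6.53 of the counts in NCD vehicle, 52.6% ± 7.68 in HFD-STZ vehicle and 45.2% ± 1.79 in HFD-STZ DHZ (mean ± SD, n = 3 each). Unprocessed pseudogenes took a further 19.1% (NCD vehicle replicate 3) to 26.2% (HFD-STZ vehicle replicate 2). Among them is Gm28661, whose count was 97.6% to 98.3% of that of mt-Co2, so reads of the mitochondrial genome and of its nuclear copies cannot be separated. Nuclear protein-coding genes were left with 6.19 ± 2.04, 4.19 ± 2.20 and 10.2 ± 4.37 M counts in the 3 groups. The lowest library was HFD-STZ vehicle replicate 2, with 2.13 M such counts, 60.4% mitochondrial counts and 19397 genes detected, against up to 26201 genes in HFD-STZ DHZ replicate 2. Malat1, a nuclear non-coding RNA, held 9.17% ± 4.84, 15.8% ± 6.80 and 4.55% ± 1.16 of the counts left after mitochondrial genes and unprocessed pseudogenes were set aside. The first 2 principal components held 42.9% and 22.4% of the variance.

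**Figure D1:**
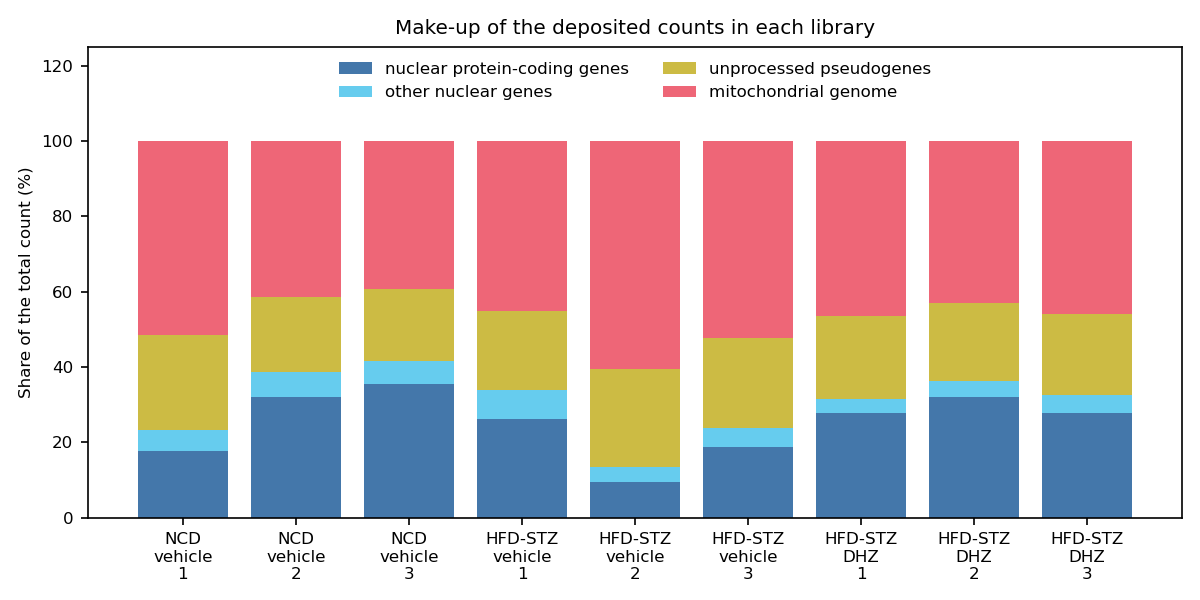
Share of the total count (percent, y axis) taken by 4 classes of genes in each of the 9 libraries (x axis, 3 per group), drawn as stacked bars. Mitochondrial counts and unprocessed pseudogenes together run from 58.3% in NCD vehicle replicate 3 to 86.6% in HFD-STZ vehicle replicate 2.

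Each group held libraries of both sexes by their transcripts. Xist, the RNA that silences an X chromosome in female cells, stood at 500.1 and 592 CPM of the total count in NCD vehicle replicates 2 and 3, at 553 in HFD-STZ vehicle replicate 1, and at 779 and 561 in HFD-STZ DHZ replicates 1 and 2. It lay below 1 in the other libraries. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d together gave 62.1 CPM of the total count in NCD vehicle replicate 1, 36.5 and 73.0 in HFD-STZ vehicle replicates 2 and 3, and 106 in HFD-STZ DHZ replicate 3. Elsewhere they gave at most 0.209. Libraries with Y-linked transcripts thus made up 1 of 3, 2 of 3 and 1 of 3 in the order of the groups. The list of sex chromosome check genes was not called in any comparison (adjusted p = 0.59 for HFD-STZ vehicle against NCD vehicle, 0.62 for HFD-STZ DHZ against HFD-STZ vehicle and 0.95 for HFD-STZ DHZ against NCD vehicle, with 0 members passing by either count). In the last of these its median (0.48) and mean (0.43) were positive while camera's direction was down. Lists of sex-biased kidney genes were not called either, with 0 members passing by either count. For male-biased genes 13 of 13 estimates were higher in HFD-STZ vehicle than in NCD vehicle (median 0.72, adjusted p = 0.094) and 9 of 13 lower in HFD-STZ DHZ than in HFD-STZ vehicle (median −0.99, adjusted p = 0.43). For female-biased genes 9 of 10 were lower in the former (median −0.93, adjusted p = 0.072) and 10 of 10 higher in the latter (median 1.32, adjusted p = 0.18).

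What the diabetic model changed was asked by comparing HFD-STZ vehicle with NCD vehicle. Sox9, a transcription factor of injured and regenerating tubule cells, rose from 1.07 ± 0.375 to 14.4 ± 4.65 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.72 (SE 0.32, adjusted p = 8.4e-04, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). S100g, the calcium-binding protein calbindin-D9k of the distal nephron, fell from 394 ± 62.4 to 47.2 ± 9.39 CPM (log2 fold change −3.06, SE 0.28, adjusted p = 9.5e-04). A pair of proximal tubule genes fell as well. They were Slc6a19, a transporter of neutral amino acids, which went from 16.1 ± 1.76 to 4.89 ± 1.15 CPM (−1.73, SE 0.24, adjusted p = 0.035), and Acmsd, an enzyme of tryptophan breakdown, which went from 15.1 ± 2.11 to 4.65 ± 1.36 CPM (−1.73, SE 0.26, adjusted p = 0.045). The growth factor Mdk fell from 11.3 ± 0.411 to 2.87 ± 1.03 CPM (−1.92, SE 0.26, adjusted p = 0.035) and the collagen chain Col5a2 from 24.0 ± 1.91 to 9.70 ± 0.402 CPM (−1.30, SE 0.20, adjusted p = 0.046).

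A further 3 genes rose. Dzip1, which acts in cilia, went from 2.35 ± 0.346 to 9.35 ± 1.90 CPM (1.99, SE 0.30, adjusted p = 0.045). Greb1, an oestrogen-induced gene, went from 0.38 ± 0.142 to 3.15 ± 1.29 CPM (3.02, SE 0.46, adjusted p = 0.045), and Slitrk4, a membrane protein of neurons, from 0.198 ± 0.14 to 4.39 ± 0.958 CPM (4.29, SE 0.60, adjusted p = 0.035). These 9 genes were the whole set called among 17179 tested, 4 higher (44.4%) and 5 lower. All were protein-coding, changed at least 2-fold and had no overlap between the 3 libraries of either group. At an unadjusted p under 0.05 there were 1276 genes, and 1957 genes (11.4%) had no overlap between the groups, where chance gives 10%. With libraries scaled by library size only, 29 genes were called, 7 of them higher (24.1%). DESeq2 called 126 and limma-voom 2, while edgeR called 425 with no filter, 3 with only the 2 groups compared and 2 with the replicate number as a block. Settings chosen after the data were seen gave 42 (a Y-linked library term) and 15 (a GC and length offset). Fits on only the libraries with, or without, Y-linked transcripts leave 1 library in a group here and are given in the closing section. Sox9 and S100g were called whichever of the 6 libraries compared was left out (highest adjusted p = 0.0056 and 0.011). The other 7 lost their calls without any 1 of the 3 NCD vehicle libraries, when 2 genes were called. All but Greb1 also lost them without HFD-STZ vehicle replicate 3 (3 genes called), and the highest adjusted p were 0.16 (Mdk) to 0.24 (Greb1 and Dzip1). Slitrk4 lay at 4.93 without NCD vehicle replicate 3. Without HFD-STZ vehicle replicate 1, 28 genes were called. The HFD-STZ DHZ libraries share the fit, and without replicate 1, 2 or 3 of them 5, 4 and 2 of the 9 genes kept their calls.

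**Figure D2:**
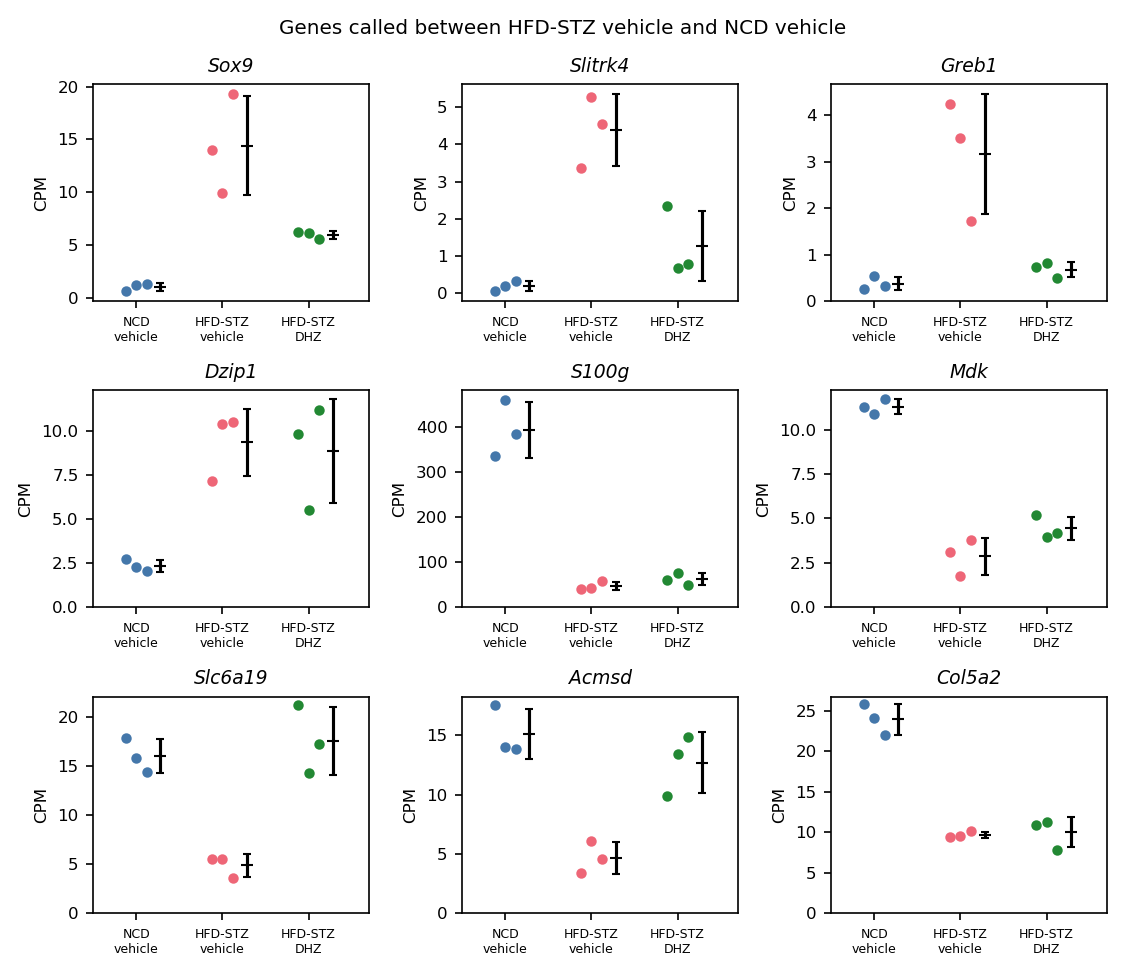
CPM (y axis, starting at 0) of the 9 genes called between HFD-STZ vehicle and NCD vehicle in every library of the 3 groups (x axis); points are libraries, and the black marks give mean ± SD of 3. Sox9 lies at 1.07 ± 0.375 CPM in NCD vehicle, 14.4 ± 4.65 in HFD-STZ vehicle and 6.00 ± 0.388 in HFD-STZ DHZ.

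Of 45 gene lists tested with camera, 14 were called between HFD-STZ vehicle and NCD vehicle, 3 higher and 11 lower. None of these calls held with an estimated correlation, under which 4 lists had an unadjusted p below 0.05 and the lowest adjusted p = 0.091; fry called 1 list. Proximal convoluted tubule markers were lower (14 tested, median log2 fold change −0.57, adjusted p = 1.9e-07; adjusted p = 0.091 with an estimated correlation; fry adjusted p = 0.017). Of them 1 fell and 0 rose over all genes, and 6 fell when adjusted over the list alone. Slc6a19 was the member that passed, whereas the glucose transporter Slc5a2 (−1.62, adjusted p = 0.052), Slc7a7 (−1.20, adjusted p = 0.11) and Slc5a12 (−1.12, adjusted p = 0.21) did not. Podocyte markers were lower as a list (15 tested, median −0.43, adjusted p = 2.3e-04; adjusted p = 0.48 with an estimated correlation), with 0 members passing over all genes and 3 lower when adjusted over the list alone. Podxl, of the podocyte surface, had −1.07 (adjusted p = 0.36), Clic5 −0.74 (adjusted p = 0.39) and Synpo −0.87 (adjusted p = 0.56). Mesangial and smooth muscle markers (11 tested, median −0.63, adjusted p = 1.3e-05; adjusted p = 0.30 with an estimated correlation) and endothelial markers (12 tested, median −0.53, adjusted p = 1.6e-05; adjusted p = 0.52 with an estimated correlation) were lower too. In these, 0 members passed over all genes, and 4 and 0 were lower when adjusted over the list alone. Pdgfrb had −1.30 (adjusted p = 0.11), Tagln −1.60 (adjusted p = 0.32) and Egfl7 −1.15 (adjusted p = 0.50).

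The fibrosis and matrix list gave the smallest p of the lists in this comparison, and it was lower, not higher, in the diabetic kidney (23 tested, median −0.55, adjusted p = 1.4e-10; adjusted p = 0.28 with an estimated correlation). No member passed over all genes and 9 were lower when adjusted over the list alone. Ccn2 had −1.22 (adjusted p = 0.11), the proteoglycans Bgn −1.28 (adjusted p = 0.15) and Dcn −0.99 (adjusted p = 0.39), and the microfibril gene Fbn1 −1.42 (adjusted p = 0.36). Complement and coagulation genes were lower (16 tested, median −0.67, adjusted p = 3.4e-04; adjusted p = 0.48 with an estimated correlation), with 0 members passing over all genes and 2 lower when adjusted over the list alone. Serping1 had −1.27 (adjusted p = 0.36). Intercalated cell markers (13 tested, median −0.27, adjusted p = 0.0066; adjusted p = 0.28 with an estimated correlation) were lower, with 0 members passing over all genes and 1 lower when adjusted over the list alone (Foxi1 −1.15, adjusted p = 0.36). Lipogenesis genes were lower (20 tested, median −0.42, adjusted p = 0.0055; adjusted p = 0.52 with an estimated correlation), with 0 members passing by either count. Cholesterol synthesis genes were lower (21 tested, median −0.40, adjusted p = 5.4e-04; adjusted p = 0.52 with an estimated correlation), with 0 members passing over all genes and 1 when adjusted over the list alone. In the lipogenesis list Fads1 had −0.76 (adjusted p = 0.40). White adipocyte markers, a check for fat on the tissue, were lower (10 tested, median −3.06, adjusted p = 4.7e-04; adjusted p = 0.52 with an estimated correlation), with 0 members passing by either count. Thrsp had −3.40 (adjusted p = 0.52). Without HFD-STZ vehicle replicate 1 the calls of lipogenesis (adjusted p = 0.22) and cholesterol synthesis (adjusted p = 0.25) were lost, and without NCD vehicle replicate 3 those of white adipocytes (median −0.42, adjusted p = 0.065) and lipogenesis.

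Higher in HFD-STZ vehicle were the 13 protein genes of the mitochondrial genome (median 1.26, adjusted p = 1.6e-07; adjusted p = 0.52 with an estimated correlation), while the cytosolic ribosome list was lower (30 tested, median −0.37, adjusted p = 1.6e-05; adjusted p = 0.58 with an estimated correlation). In both lists 0 members passed over all genes or over the list alone. The median of the first was 0.41 without HFD-STZ vehicle replicate 2 (adjusted p = 0.0039) and 1.97 without NCD vehicle replicate 1. The mitochondrial gene mt-Nd5 had 2.04 (SE 0.81, adjusted p = 0.61) and Rpl3 −0.65 (SE 0.25, adjusted p = 0.60). The HFD-STZ vehicle libraries had the higher mitochondrial share, 52.6% ± 7.68 against 44.0% ± 6.53, and 4.19 ± 2.20 against 6.19 ± 2.04 M nuclear coding counts. The tubular injury list was called higher (14 tested, mean 0.63, median 0.09, adjusted p = 0.0045; adjusted p = 0.52 with an estimated correlation) with 1 member, Sox9, passing by either count. Cxcl1 had 2.89 (SE 1.67, adjusted p = 0.74) and Lcn2 0.96 (SE 0.93, adjusted p = 0.82). Its call was lost without NCD vehicle replicate 1 (adjusted p = 0.12). The apoptosis and p53 list was called higher (17 tested, median 0.29, adjusted p = 0.0077; adjusted p = 0.52 with an estimated correlation), with 0 members passing over all genes and 1 higher when adjusted over the list alone. The cell cycle inhibitor Cdkn1a had 1.69 (SE 0.40, adjusted p = 0.22). The call of the list was lost without HFD-STZ vehicle replicate 3 (adjusted p = 0.15). With library size only the median log2 fold change of all genes was −0.74. This scaling turned the medians of tubular injury to −0.72 and of apoptosis and p53 to −0.42, although camera, which compares with other genes, still called both higher. The list for the glomerular basement membrane and junctions was not called (adjusted p = 0.23), with 0 members passing over all genes and 1 lower when adjusted over the list alone (Nid1 −1.68, adjusted p = 0.26). Inflammatory cytokines and NF-kB (adjusted p = 0.45) and the NRF2 antioxidant response (adjusted p = 0.055) were not called either, with 0 members passing by either count. Nfkbia had 0.47 (adjusted p = 0.71), Nqo1 1.09 (adjusted p = 0.42) and Gstm1 0.96 (adjusted p = 0.40). In the list of the distal convoluted and connecting tubule, which holds S100g and was not called (adjusted p = 0.17), the median was 0.15 but the mean −0.23 and the test's direction down.

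What dehydrozingerone changed in diabetic kidneys was asked by comparing HFD-STZ DHZ with HFD-STZ vehicle. Clic5, a chloride channel protein of podocyte foot processes, rose from 7.82 ± 0.584 to 22.7 ± 3.15 CPM (mean ± SD, n = 3 per group; log2 fold change 1.53, SE 0.21, adjusted p = 0.0031). The lysosomal genes Ctsl, a protease, and Lamp1, a membrane protein, rose from 28.6 ± 7.01 to 121 ± 9.42 CPM (2.08, SE 0.24, adjusted p = 0.0031) and from 38.6 ± 6.21 to 152 ± 17.6 CPM (1.98, SE 0.29, adjusted p = 0.0031). Slc6a19 rose from 4.89 ± 1.15 to 17.6 ± 3.48 CPM (1.86, SE 0.24, adjusted p = 0.0031). Nfkbia, the inhibitor that NF-kB itself induces, fell from 55.1 ± 9.22 to 21.2 ± 6.14 CPM (−1.37, SE 0.26, adjusted p = 0.0066).

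In all, 3796 of 17179 genes were called, 1726 higher (45.5%) and 2070 lower, of which 1054 and 1542 changed at least 2-fold. At an unadjusted p under 0.05 there were 6366, and 6843 (39.8%) had no overlap between the groups, where chance gives 10%. Protein-coding genes made up 1548 of the genes called higher and 1205 of those called lower, and other classes 178 and 865. Scaled by library size only, 888 genes were called and 832 of them (93.7%) were higher, with a median log2 fold change of all genes of 0.81 against 0.04 with TMM. Directions given here are relative to the TMM scaling. Among called genes with a mean log2 CPM of at least 1, those that rose most include Kynu of tryptophan breakdown (2.58, SE 0.56), the proliferation marker Mki67 (2.46, SE 0.71), the glypican Gpc3 (2.42, SE 0.39) and the fibrinogen chain Fga (2.41, SE 0.36). They also include Spp1, which encodes osteopontin (2.37, SE 0.59), Tgfbi of the matrix (2.35, SE 0.50), the vitamin D carrier Gc (2.30, SE 0.70), Spcs1 of the signal peptidase (2.26, SE 0.28) and Emp1 (2.24, SE 0.35), and adjusted p of these genes ran from 0.0031 to 0.045. Among those that fell most were the pseudogenes Hmgb1-rs16 (−3.06, SE 0.47, adjusted p = 0.0039) and Rpl28-ps3 (−3.22, adjusted p = 0.044) and the arrestin-like gene Arrdc2 (−3.02, SE 0.44, adjusted p = 0.0031). Trim30a (−3.64, adjusted p = 0.022), Trim30c (−3.51, adjusted p = 0.032), Trim12c (−3.37, adjusted p = 0.027), Trim30b (−3.35, adjusted p = 0.049) and Trim34a (−3.03, adjusted p = 0.030) belong to the same gene family. How reads that fit several genes were counted is not given in the sources used here, so their values and those of both pseudogenes are uncertain. HFD-STZ vehicle replicate 2 held 8901 CPM of Trim30a against at most 1299.7 in any other library. Without it the fold changes were −1.66 (Trim30a), −1.51 (Trim30c), −1.43 (Trim12c), −1.24 (Trim30b, adjusted p = 0.077), −1.43 (Trim34a) and −1.30 (Rpl28-ps3).

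Without HFD-STZ DHZ replicate 1 or 2 the count of called genes was 1149 or 1302, and with the replicate number as a block 2159. Of the 3796 calls, 3674, 3027 and 3128 held without NCD vehicle replicates 1, 2 and 3, which share the fit. Fits on only the libraries with, or without, Y-linked transcripts, chosen after the data were seen, leave 1 library in a group here. Their counts differ widely and are given in the closing section. Kynu, Gpc3, Fga, Tgfbi, Spcs1, Emp1, Hmgb1-rs16 and Arrdc2 kept their calls whichever library was left out. Spp1 lost its call without HFD-STZ vehicle replicate 1 (adjusted p = 0.052) and lay at 1.30 without HFD-STZ DHZ replicate 3. Mki67 lost its call without any 1 of the HFD-STZ vehicle libraries or HFD-STZ DHZ replicate 3 (highest adjusted p = 0.11), when it lay at 1.17 in the last case. The call of Gc ended without HFD-STZ vehicle replicate 2 or 3 or HFD-STZ DHZ replicate 1 or 2 (highest adjusted p = 0.14). The Trim genes and Rpl28-ps3 lost theirs without HFD-STZ DHZ replicate 1 or 2. Trim30c, Trim30b and Rpl28-ps3 also lost theirs without replicate 3 and Trim30b without HFD-STZ vehicle replicate 2, with highest adjusted p from 0.084 (Trim30a) to 0.15 (Rpl28-ps3).

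**Figure D3:**
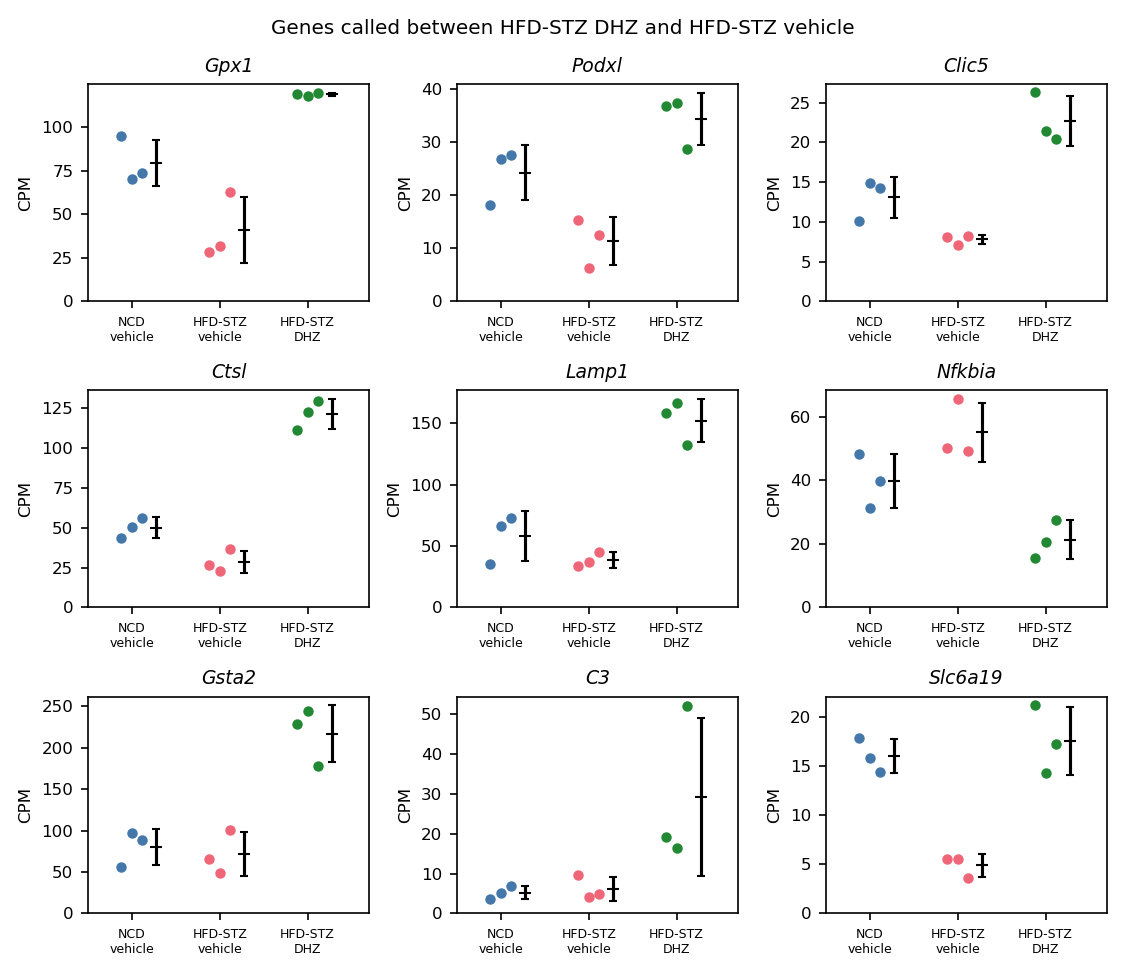
CPM (y axis, starting at 0) of 9 genes called between HFD-STZ DHZ and HFD-STZ vehicle in every library of the 3 groups (x axis); points are libraries, and the black marks give mean ± SD of 3. Slc6a19 lies at 16.1 ± 1.76 CPM in NCD vehicle, 4.89 ± 1.15 in HFD-STZ vehicle and 17.6 ± 3.48 in HFD-STZ DHZ.

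Of the 45 lists, 14 were called between HFD-STZ DHZ and HFD-STZ vehicle, 13 higher and 1 lower. The libraries also differed in mitochondrial share (45.2% ± 1.79 against 52.6% ± 7.68), in nuclear coding counts (10.2 ± 4.37 against 4.19 ± 2.20 M) and in libraries with Y-linked transcripts (1 of 3 against 2 of 3). Each of these calls was lost with an estimated correlation (adjusted p = 0.68 with an estimated correlation for all 14), under which 1 list had an unadjusted p below 0.05. Fry called 5 lists. Proximal convoluted tubule, complement and coagulation, and AMPK, autophagy and lysosome were among them. The others, AHR and xenobiotic and hypoxia and VEGF, were not called by camera. Leaving out HFD-STZ vehicle replicate 2 gave 8 lists, and nuclear protein-coding genes only, chosen after the data were seen, 7. Proximal convoluted tubule markers were higher (14 tested, median 0.47, adjusted p = 0.023). Over all genes 5 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone. Those that rose include Slc7a7 (1.15, adjusted p = 0.0072), Gatm of creatine synthesis (0.97, adjusted p = 0.018) and Slc5a2 (0.98, SE 0.25, adjusted p = 0.019). Complement and coagulation genes were higher (16 tested, median 0.92, adjusted p = 0.0041), with 5 members rising over all genes and 6 when adjusted over the list alone. C3, the central complement protein, went from 6.18 ± 2.97 to 29.2 ± 19.8 CPM (2.22, SE 0.48, adjusted p = 0.011). The complement protease Cfi (2.95, adjusted p = 0.0064), the tissue factor gene F3 (1.35, adjusted p = 0.0081) and Thbd (1.52, adjusted p = 0.012) rose too. Macrophage and dendritic cell markers were higher (13 tested, median 1.00, adjusted p = 0.0052), with 4 rising and 1 falling over all genes and 7 and 1 when adjusted over the list alone. Mpeg1 rose by 1.28 (adjusted p = 0.0088) and the complement components C1qb by 1.60 (adjusted p = 0.0096), C1qc by 1.28 (adjusted p = 0.014) and C1qa by 1.86 (adjusted p = 0.019). Antigen presentation genes were higher (15 tested, median 0.37, adjusted p = 0.038). The class II genes H2-Eb1 (1.62, adjusted p = 0.0086), H2-Aa (1.30, adjusted p = 0.012) and H2-Ab1 (1.08, adjusted p = 0.027) were the 3 that rose by either count. Left out singly, HFD-STZ DHZ replicate 1 and replicate 2 ended the calls of Gatm and Slc5a2 (highest adjusted p = 0.072 and 0.064), and replicate 1 that of Thbd (adjusted p = 0.057). The call of C1qa ended without HFD-STZ vehicle replicate 3 or any HFD-STZ DHZ library (highest adjusted p = 0.054), and that of H2-Ab1 without HFD-STZ vehicle replicate 2 or 3 or HFD-STZ DHZ replicate 1 or 3 (highest adjusted p = 0.097). Without HFD-STZ DHZ replicate 3 the values of C3 and Cfi were 1.51 and 2.22, still called (adjusted p = 0.020 and 0.012), and without HFD-STZ vehicle replicate 1 that of C1qa was 2.46. The antigen presentation list lost its call without HFD-STZ vehicle replicate 2 or 3 or HFD-STZ DHZ replicate 3 (highest adjusted p = 0.21). White adipocyte markers, the check for fat on the tissue, were not called (10 tested, median 2.69, adjusted p = 0.090), with 9 of 10 estimates higher, 1 member rising over all genes and 0 when adjusted over the list alone.

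Podocyte markers were not called as a list after treatment (15 tested, median 0.30, adjusted p = 0.18), but 6 members rose and 3 fell, over all genes and when adjusted over the list alone. Beside Clic5, Podxl rose from 11.4 ± 4.58 to 34.2 ± 4.90 CPM (1.57, SE 0.30, adjusted p = 0.0066). Cdkn1c, a cell cycle inhibitor of mature podocytes, fell from 17.1 ± 2.36 to 7.91 ± 0.91 CPM (−1.11, SE 0.19, adjusted p = 0.0050). The list for the glomerular basement membrane and junctions was not called either (18 tested, adjusted p = 0.14), with 7 members rising and 1 falling over all genes and 7 and 2 when adjusted over the list alone. The claudin Cldn2 (1.31, SE 0.23, adjusted p = 0.0056), nidogen Nid1 (1.97, adjusted p = 0.0084), the integrin Itgb1 (1.11, adjusted p = 0.0091) and Ocln of tight junctions (1.21, adjusted p = 0.012) rose. Fibrosis and matrix genes were higher as a list (23 tested, median 0.68, adjusted p = 0.0041; adjusted p = 0.68 with an estimated correlation), with 7 rising over all genes and 9 when adjusted over the list alone. Fibronectin (Fn1) went from 2.60 ± 0.0811 to 6.95 ± 2.02 CPM (1.42, SE 0.30, adjusted p = 0.0094). Col3a1 rose by 1.80 (SE 0.41, adjusted p = 0.012) and Bgn by 1.05 (adjusted p = 0.019). Tubular injury genes were not called as a list (14 tested, median 0.86, adjusted p = 0.097), and 3 rose and 1 fell by either count. Those that rose were Spp1, the lipid droplet gene Plin2 (0.79, adjusted p = 0.024) and the adhesion molecule Vcam1 (1.87, adjusted p = 0.048), and Sox9 fell (−1.28, SE 0.28, adjusted p = 0.010). Inflammatory cytokine and NF-kB genes were not called (16 tested, adjusted p = 0.47). Over all genes Vcam1 rose, and Nfkbia and Nfkb1 (−0.96, adjusted p = 0.016) fell. When adjusted over the list alone, 0 rose and 2 fell, and Tlr2 did not pass over all genes (1.75, adjusted p = 0.061). The call of Ocln (highest adjusted p = 0.053) and that of Nfkb1 (highest adjusted p = 0.081) ended without HFD-STZ DHZ replicate 1 or 2, and that of Bgn without HFD-STZ DHZ replicate 1 or HFD-STZ vehicle replicate 3 (highest adjusted p = 0.088). That of Plin2 ended without HFD-STZ vehicle replicate 1 or any HFD-STZ DHZ library (highest adjusted p = 0.077), and that of Vcam1 without any HFD-STZ vehicle library or HFD-STZ DHZ replicate 3 (highest adjusted p = 0.15). Without HFD-STZ DHZ replicate 3 Vcam1 lay at 0.72 and Col3a1, still called, at 1.08 (adjusted p = 0.021).

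NRF2 antioxidant genes were higher in HFD-STZ DHZ (24 tested, median 0.61, adjusted p = 0.0052; adjusted p = 0.68 with an estimated correlation). Over all genes 7 rose and 2 fell, and 10 and 2 when adjusted over the list alone. Gsta2, a glutathione transferase with close paralogs, went from 71.8 ± 26.5 to 217 ± 34.4 CPM (1.60, SE 0.32, adjusted p = 0.0074). Gpx1, a glutathione peroxidase, went from 40.8 ± 18.9 to 119 ± 0.843 CPM (1.54, SE 0.30, adjusted p = 0.0070), and Nfe2l2, which encodes NRF2, from 17.8 ± 3.40 to 35.9 ± 6.74 CPM (1.02, SE 0.22, adjusted p = 0.010). The AMPK, autophagy and lysosome list was higher (22 tested, median 0.44, adjusted p = 0.021; adjusted p = 0.68 with an estimated correlation), with 6 rising and 2 falling over all genes and 7 and 2 when adjusted over the list alone. Risen members were the AMPK subunit Prkaa2 (1.11, SE 0.20, adjusted p = 0.0056) and the deacetylase Sirt1 (0.88, SE 0.20, adjusted p = 0.011) beside Ctsl and Lamp1. Cell cycle genes were higher (15 tested, median 1.15, adjusted p = 0.0052; adjusted p = 0.68 with an estimated correlation), with 4 rising by either count. Pcna, the replication clamp, rose from 4.50 ± 0.514 to 13.4 ± 1.85 CPM (1.56, SE 0.22, adjusted p = 0.0031). The replication genes Mcm5 (2.41, adjusted p = 0.018) and Mcm6 (1.58, adjusted p = 0.019) rose beside Mki67. In the renin-angiotensin list (10 tested, median 0.85, adjusted p = 0.038; adjusted p = 0.68 with an estimated correlation) 5 rose and 1 fell by either count. Renin (Ren1) rose by 1.47 (SE 0.34, adjusted p = 0.013) and the receptor Agtr1a by 1.04 (adjusted p = 0.013), and angiotensinogen (Agt) fell by 0.89 (adjusted p = 0.024). Apoptosis and p53 genes were higher (17 tested, median 0.52, adjusted p = 0.038; adjusted p = 0.68 with an estimated correlation). By either count 3 rose, Ccng1 (1.26, adjusted p = 0.0061) and Trp53inp1 (1.14, adjusted p = 0.0091) among them. Without HFD-STZ vehicle replicate 1 the call of the NRF2 list was lost (adjusted p = 0.064), and without HFD-STZ DHZ replicate 3 that of the cell cycle (median 0.51, adjusted p = 0.086). Without HFD-STZ vehicle replicate 1 or 2 the calls of AMPK, renin-angiotensin and p53 were lost, that of renin-angiotensin also without HFD-STZ DHZ replicate 1 and that of p53 without replicate 3 (highest adjusted p = 0.060, 0.064 and 0.14). Without HFD-STZ DHZ replicate 1 the calls of Nfe2l2 (adjusted p = 0.052) and Ren1 (adjusted p = 0.062) were lost, and without replicate 1 or 2 those of Agtr1a, Mcm5 and Mcm6 (highest adjusted p = 0.060, 0.056 and 0.069). Mcm5 also lost its call without HFD-STZ vehicle replicate 1 and Mcm6 without replicate 3, when Mcm5 lay at 3.20. The call of Agt ended without HFD-STZ vehicle replicate 3 or HFD-STZ DHZ replicate 1 or 3 (highest adjusted p = 0.10).

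Nuclear-encoded oxidative phosphorylation genes were higher in HFD-STZ DHZ (30 tested, median 0.48, adjusted p = 0.0059; adjusted p = 0.68 with an estimated correlation), with 7 rising and 1 falling by either count. Cox5a rose by 2.04 (adjusted p = 0.0074), Sdha by 1.12 (adjusted p = 0.010), Sdhd by 1.07 (adjusted p = 0.014) and Atp5b by 1.12 (adjusted p = 0.015). Glycolysis genes were higher (14 tested, median 0.62, adjusted p = 0.023; adjusted p = 0.68 with an estimated correlation), with 4 rising over all genes and 6 rising and 1 falling when adjusted over the list alone. Pgk1 (1.42, adjusted p = 0.0069) and Tpi1 (1.44, adjusted p = 0.0087) rose. Cytosolic ribosome genes were higher (30 tested, median 0.50, adjusted p = 0.0041; adjusted p = 0.68 with an estimated correlation), 7 rising by either count, with Rpl3 at 1.44 (adjusted p = 0.0056) and Rps23 at 1.16 (adjusted p = 0.017). The mitochondrial genome was the 1 list called lower (13 tested, median −1.42, adjusted p = 0.0052; adjusted p = 0.68 with an estimated correlation). In it mt-Nd6 fell by 1.26 (SE 0.39, adjusted p = 0.037), the only member to pass over all genes, and 0 passed when adjusted over the list alone. The member mt-Nd2 had −1.99 (SE 0.81, adjusted p = 0.096). Without HFD-STZ vehicle replicate 2 the calls of the mitochondrial genome (median −0.62, adjusted p = 0.13) and glycolysis (adjusted p = 0.069) were lost, and without HFD-STZ vehicle replicate 1 that of oxidative phosphorylation (adjusted p = 0.051). Sdha (adjusted p = 0.050) lost its call without HFD-STZ DHZ replicate 1, Sdhd, Atp5b and Rps23 without replicate 1 or 2 (highest adjusted p = 0.062, 0.069 and 0.071), and mt-Nd6 without any library but HFD-STZ vehicle replicate 1 (highest adjusted p = 0.12).

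**Figure D4:**
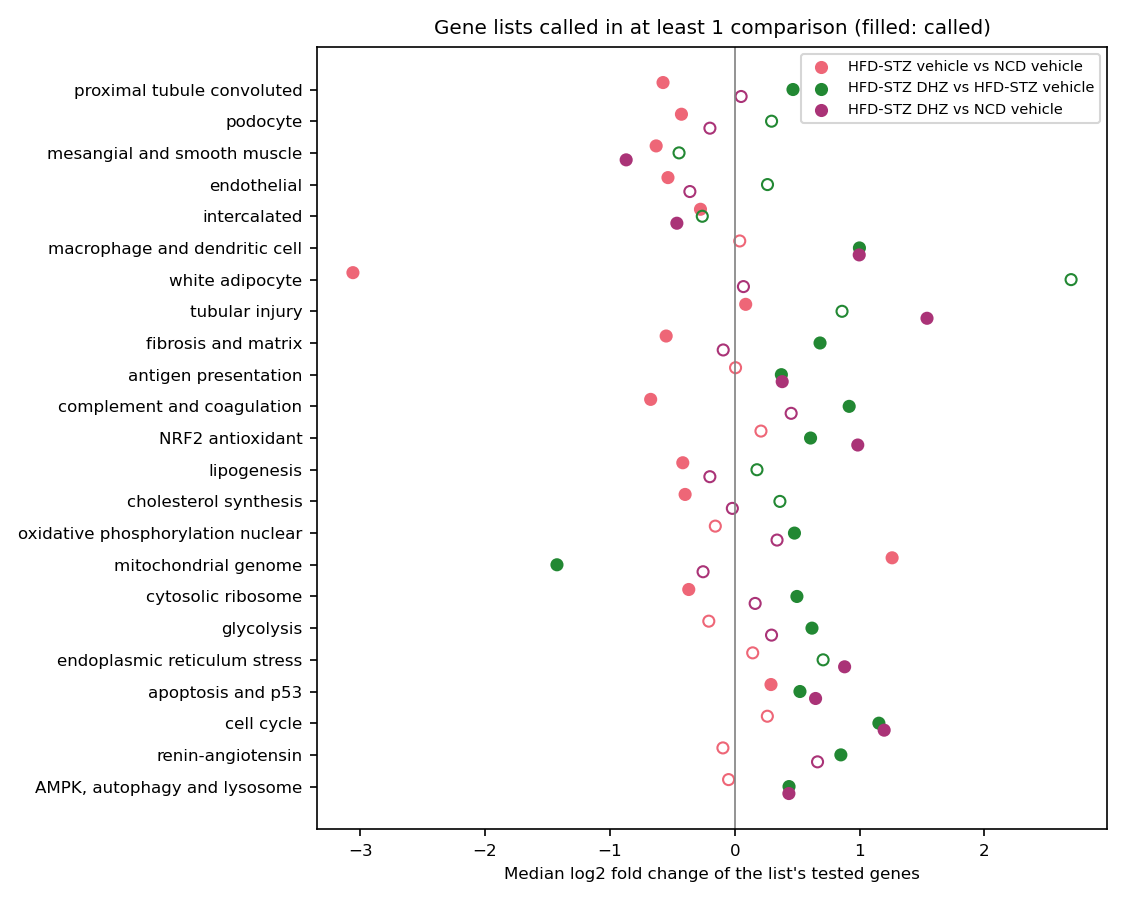
Median log2 fold change (x axis) of the tested genes of 23 gene lists (y axis) that camera called in at least 1 comparison; colours are the 3 comparisons, and filled points mark the lists called in that comparison. The fibrosis and matrix list lies at −0.55 between HFD-STZ vehicle and NCD vehicle and at 0.68 between HFD-STZ DHZ and HFD-STZ vehicle.

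Whether treatment moved the model's genes back was asked by setting both comparisons side by side. Of the 9 genes called in the model, 5 were called in the opposite direction by treatment and 0 in the same. Slc6a19 (−1.73, then 1.86) and Acmsd (−1.73, then 1.48) fell and then rose. Sox9 (3.72, then −1.28), Greb1 (3.02, then −2.17) and Slitrk4 (4.29, then −1.78) rose and then fell, Slitrk4 by 2.54 in the second step without HFD-STZ DHZ replicate 1. All 9 had a treatment estimate of opposite sign, but 4 did not pass, namely S100g (0.41, adjusted p = 0.27), Mdk (0.58, adjusted p = 0.13), Dzip1 (−0.08, adjusted p = 0.86) and Col5a2 (0.05, adjusted p = 0.89). These 4, Sox9 and Slitrk4 were still called in the same direction between HFD-STZ DHZ and NCD vehicle. Sox9 was higher there by 2.44 (adjusted p = 0.0083) and S100g lower (−2.65, adjusted p = 0.0031), whereas Slc6a19 (0.13, adjusted p = 0.73), Acmsd (−0.25, adjusted p = 0.50) and Greb1 (0.85, adjusted p = 0.22) were not called. Independent lists would share 0.984 genes with opposite signs, and libraries simulated without effects gave 0.06 on average and at most 1. The simulation holds no treatment effect, so it can hardly call a gene in both comparisons, and these values are no bound for chance. In a test chosen after the result was seen, the HFD-STZ DHZ group was kept and the other libraries were split in all 20 ways. Of these splits 4, the real one included, gave at least 5, and the highest other gave 9. They were the real grouping with either part as the shared group (5, and 6 with NCD vehicle shared). The rest were the Xist-expressing against the Y-linked libraries, with either part shared (8 and 9). All other splits gave 0. The count of opposite genes was 13 without HFD-STZ vehicle replicate 1, 2 without HFD-STZ vehicle replicate 3, and 1 without any 1 of the NCD vehicle libraries or HFD-STZ DHZ replicate 2 or 3. It was 9 with library size only, 262 with no filter, 64 with DESeq2, 1 with limma-voom and 1 with the replicate number as a block. Settings chosen after the data were seen gave 23 (a Y-linked library term), 8 (nuclear protein-coding genes only) and 8 (a GC and length offset). Libraries without Y-linked transcripts only leave 1 HFD-STZ vehicle library for both comparisons to share, and that fit is given in the closing section. Across genes, which are not independent replicates, the fold changes of both comparisons had a correlation of −0.54, where simulation without effects gave −0.54 on average (−0.58 to −0.48), because both use the HFD-STZ vehicle libraries. Their covariance was −0.283 against −0.112 simulated (−0.125 to −0.091). A group of 3 cannot be divided to leave 2 libraries on each side, so part of the excess can come from the shared libraries.

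How the treated diabetic kidney differed from the healthy one was asked by comparing HFD-STZ DHZ with NCD vehicle. Pck1, the rate-limiting enzyme of glucose production, rose from 213 ± 66.4 to 1252 ± 141 CPM (mean ± SD, n = 3 per group; log2 fold change 2.56, SE 0.39, adjusted p = 0.0083). Ccng1, a p53 target, rose from 27.8 ± 0.649 to 101 ± 16.5 CPM (1.86, SE 0.24, adjusted p = 0.0083), and the glutathione transferase Gsta1, which has close paralogs, from 11.9 ± 2.53 to 33.0 ± 7.08 CPM (1.47, SE 0.25, adjusted p = 0.0096). Lower than in healthy kidney were S100g, at 62.8 ± 12.9 against 394 ± 62.4 CPM, and the smooth muscle myosin Myh11, at 4.57 ± 0.462 against 14.1 ± 4.01 CPM (−1.63, SE 0.25, adjusted p = 0.0083). Of 17179 genes, 2352 were called, 1084 higher (46.1%) and 1268 lower, with 583 and 958 of them at least 2-fold. Protein-coding genes gave 1020 and 714 of these calls, and other classes 64 and 554. At an unadjusted p under 0.05 there were 5454 genes, and 7571 (44.1%) had no overlap between the groups, where chance gives 10%. Scaled by library size only, 36 genes were called. DESeq2 called 3530, and edgeR 3981 with only the 2 groups compared and 772 with the replicate number as a block. Settings chosen after the data were seen gave 3617 (a Y-linked library term) and 4869 (libraries without Y-linked transcripts only, 2 against 2). Libraries with Y-linked transcripts only are 1 against 1 here, and that fit is given in the closing section. The count of called genes was 259 and 779 without NCD vehicle replicates 1 and 2. It was 112 and 245 without HFD-STZ DHZ replicates 1 and 2. Of the 2352 calls, 2290, 2332 and 2189 held without HFD-STZ vehicle replicates 1, 2 and 3, which share the fit.

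Among called genes with a mean log2 CPM of at least 1, those that rose most against NCD vehicle were the chemokine Ccl28 (3.71, SE 0.98), the vitamin D hydroxylase Cyp24a1 (3.22, SE 0.70), Gc (2.81), Hmox1, which breaks down haem (2.71, SE 0.70), and Fga (2.62, SE 0.36). Next were Mki67 (2.57), Pck1, C3 (2.49, SE 0.48), Sox9 and the carboxylesterase Ces2e (2.29, SE 0.38), with adjusted p from 0.0083 to 0.043. Cyp24a1 went from 7.01 ± 1.72 to 65.5 ± 37.6 CPM and Hmox1 from 1.18 ± 0.275 to 7.66 ± 5.57 CPM. Those that fell most were the pseudogene Hmgb1-rs16 (−2.79), S100g, the AMPK subunit Prkag3 (−2.61), the cytochrome Cyp2d12 (−2.55, SE 0.37), Sec14l3 (−2.32), Chkb of phospholipid synthesis (−2.18) and the activin receptor Acvr2b (−2.16). They also include the pseudogene Rpl23a-ps2 (−2.16), Selenok-ps1 (−2.14), classed as a processed transcript, and the homeobox gene Hoxc9 (−2.09, SE 0.32), with adjusted p from 0.0031 to 0.022. Values of the pseudogenes are uncertain here too. Fga, Pck1, Sox9, Ces2e, Hmgb1-rs16, S100g, Cyp2d12, Rpl23a-ps2 and Hoxc9 were called whichever library was left out. Of the others, C3 lost its call without NCD vehicle replicate 1 (adjusted p = 0.060). Chkb, Acvr2b and Selenok-ps1 lost theirs without HFD-STZ DHZ replicate 1 or 2 (highest adjusted p = 0.059, 0.061 and 0.054). Prkag3 lost it without these or NCD vehicle replicate 1 (highest adjusted p = 0.076), and Sec14l3 also without NCD vehicle replicate 2 (highest adjusted p = 0.077). Cyp24a1, Gc, Hmox1, Mki67 and Ccl28 lost theirs without any 1 of the NCD vehicle libraries, with highest adjusted p from 0.086 (Cyp24a1) to 0.14 (Ccl28). Of the HFD-STZ DHZ libraries, replicate 1 ended the calls of Cyp24a1, Gc, Mki67 and Ccl28, replicate 2 those of Gc, Hmox1 and Ccl28, and replicate 3 those of Hmox1, Mki67 and Ccl28. Without replicate 3 Mki67 lay at 1.29, Hmox1 at 2.09 and C3, still called, at 1.79 (adjusted p = 0.021). Without NCD vehicle replicate 1 Prkag3 lay at −1.78 and Chkb at −1.53 (adjusted p = 0.041), and without NCD vehicle replicate 3 Ccl28 at 4.53.

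Between HFD-STZ DHZ and NCD vehicle 10 lists were called, 8 higher and 2 lower. All were lost with an estimated correlation, under which 3 lists had an unadjusted p below 0.05. Fry called 5. Camera called 22 without HFD-STZ DHZ replicate 1, 18 with library size only, 20 with no filter and 17 with only the libraries without Y-linked transcripts, a setting chosen after the data were seen. Here mitochondrial shares were 45.2% ± 1.79 and 44.0% ± 6.53, nuclear coding counts 10.2 ± 4.37 and 6.19 ± 2.04 M, and 1 of 3 libraries in each group had Y-linked transcripts. NRF2 antioxidant genes were higher (24 tested, median 0.99, adjusted p = 1.2e-05; adjusted p = 0.62 with an estimated correlation), 10 rising and 1 falling over all genes and 14 and 1 when adjusted over the list alone. Txnrd1, a thioredoxin reductase (1.15, SE 0.26, adjusted p = 0.019), Nfe2l2 (1.07, adjusted p = 0.015) and Gsta2 (1.43, adjusted p = 0.017) rose beside Gsta1. Apoptosis and p53 genes were higher (17 tested, median 0.65, adjusted p = 8.4e-05; adjusted p = 0.62 with an estimated correlation), 5 rising over all genes and 8 when adjusted over the list alone. Trp53inp1 rose by 1.70 (adjusted p = 0.0083), Eda2r by 2.18 (adjusted p = 0.011) and Cdkn1a by 1.86 (adjusted p = 0.015). Tubular injury genes were higher (14 tested, median 1.54, adjusted p = 2.8e-04; adjusted p = 0.62 with an estimated correlation), with 3 rising over all genes (Sox9, Spp1 by 2.20 and Plin2 by 0.94) and 11 when adjusted over the list alone. HFD-STZ DHZ replicate 3 was the highest of the 9 libraries for 10 of the 14, and without it Spp1 lay at 1.13 and the median of the list at 0.81. The list was called whichever library was left out (highest adjusted p = 0.0037, without this library). Cell cycle genes were higher (15 tested, median 1.20, adjusted p = 4.3e-04; adjusted p = 0.62 with an estimated correlation), 5 rising over all genes and 10 when adjusted over the list alone. Pcna rose by 1.20 (adjusted p = 0.010), Rrm2 by 1.90 (adjusted p = 0.030) and Kif11 by 3.17 (adjusted p = 0.040). Endoplasmic reticulum stress genes were higher (18 tested, median 0.88, adjusted p = 0.0077; adjusted p = 0.62 with an estimated correlation), 7 rising over all genes and 10 when adjusted over the list alone. Asns, which makes asparagine, rose by 2.82 (SE 0.58, adjusted p = 0.014), Dnajb9 by 1.03 (adjusted p = 0.022) and Xbp1 by 1.04 (adjusted p = 0.023). Among these genes Trp53inp1 and Eda2r were called whichever library was left out. Pcna lost its call without HFD-STZ DHZ replicate 2 (adjusted p = 0.053), Cdkn1a without it or NCD vehicle replicate 1 or 2 (highest adjusted p = 0.058). Txnrd1, Gsta2 and Asns lost theirs without NCD vehicle replicate 1 or HFD-STZ DHZ replicate 1 or 2 (highest adjusted p = 0.081, 0.076 and 0.073), with Asns at 2.10 without the last of these. Nfe2l2, Plin2, Dnajb9 and Xbp1 lost theirs without these or NCD vehicle replicate 2 (highest adjusted p = 0.10, Dnajb9), and Spp1, Rrm2 and Kif11 without any 1 library (highest adjusted p = 0.12, Kif11).

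Mesangial and smooth muscle markers were lower in HFD-STZ DHZ than in NCD vehicle (11 tested, median −0.87, adjusted p = 6.3e-04; adjusted p = 0.62 with an estimated correlation; fry adjusted p = 0.032), 4 falling over all genes and 6 when adjusted over the list alone. Ebf1 (−1.08, adjusted p = 0.011), Gata3 (−0.92, adjusted p = 0.016) and the smooth muscle actin Acta2 (−1.12, adjusted p = 0.021) fell with Myh11. Intercalated cell markers were lower (13 tested, median −0.46, adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation; fry adjusted p = 0.032), 3 falling over all genes and 4 when adjusted over the list alone. Those 3 were the anion exchanger Slc4a9 (−1.48, adjusted p = 0.017), Insrr (−1.53, adjusted p = 0.027) and the ammonium transporter Rhbg (−1.24, adjusted p = 0.029). Macrophage and dendritic cell markers were higher (13 tested, median 1.00, adjusted p = 0.0042; adjusted p = 0.69 with an estimated correlation), with 4 rising and 1 falling over all genes and 5 and 1 when adjusted over the list alone. The member with the lowest p, the colony stimulating factor receptor Csf1r, fell (−1.64, SE 0.31, adjusted p = 0.012), and Lyz2 rose by 1.75 (adjusted p = 0.024). Antigen presentation genes were higher (15 tested, median 0.38, adjusted p = 0.037; adjusted p = 0.77 with an estimated correlation), with H2-Eb1 (1.32) and H2-Aa (1.11) as the 2 that rose by either count. That call was lost without HFD-STZ DHZ replicate 3 (adjusted p = 0.30). The AMPK, autophagy and lysosome list was higher (22 tested, median 0.43, adjusted p = 0.023; adjusted p = 0.62 with an estimated correlation), with 4 rising and 2 falling over all genes and 6 and 2 when adjusted over the list alone. In it Lamp1 (1.39), Ctsl (1.28) and Prkaa2 (1.20) rose, and the mitochondrial deacetylase Sirt3 fell (−0.98, adjusted p = 0.024). Calls were lost without HFD-STZ DHZ replicate 1 or 2 for Ebf1 and Csf1r (highest adjusted p = 0.060 and 0.059), and without these or NCD vehicle replicate 1 for Slc4a9 and Lamp1 (highest adjusted p = 0.084 and 0.063). Ctsl and Gata3 lost theirs without replicate 1 of either group (highest adjusted p = 0.051 and 0.088), Prkaa2 without HFD-STZ DHZ replicate 1 (adjusted p = 0.051), Lyz2 without replicate 1 or 2 of either group (highest adjusted p = 0.094), and Acta2 without NCD vehicle replicate 1 or 3 or HFD-STZ DHZ replicate 1 or 2 (highest adjusted p = 0.099). Those of Insrr, H2-Eb1 and Sirt3 ended without any library but NCD vehicle replicate 3, and those of Rhbg and H2-Aa without any 1 library (highest adjusted p = 0.12, H2-Aa).

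Podocyte markers were not called between HFD-STZ DHZ and NCD vehicle (15 tested, median −0.20, adjusted p = 0.81), with 2 rising and 4 falling by either count. Cdkn1c fell (−1.13, adjusted p = 0.0093) whichever library was left out. Fibrosis and matrix genes were not called (adjusted p = 1.00, median −0.09, mean 0.06). Of them Col3a1 rose over all genes by 1.36 (adjusted p = 0.042), a call lost without any library but HFD-STZ DHZ replicate 2 (highest adjusted p = 0.13; 0.64 on the log2 scale without replicate 3), and 0 rose when adjusted over the list alone. The glomerular basement membrane and junctions list was not called (adjusted p = 0.36), with 4 rising and 1 falling over all genes and 4 and 3 when adjusted over the list alone. Ocln rose by 1.44 (adjusted p = 0.011), a call lost without HFD-STZ DHZ replicate 1 or 2 (highest adjusted p = 0.059). Inflammatory cytokines and NF-kB were not called either (adjusted p = 0.19), with 1 rising and 2 falling over all genes and 2 and 2 when adjusted over the list alone. The chemokine Cxcl10 rose by 1.90 (adjusted p = 0.035), a call lost without any 1 library (highest adjusted p = 0.13), and lay at 1.14 without HFD-STZ DHZ replicate 3. Nfkbia (−0.90, adjusted p = 0.039) and Nfkb1 (−0.77, adjusted p = 0.048) fell, calls lost without any library but HFD-STZ DHZ replicate 3 (highest adjusted p = 0.17 and 0.19). Proximal convoluted tubule markers were not called (adjusted p = 0.86), with 0 members passing by either count, a median of 0.05, a mean of −0.09 and a test direction of down.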

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

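Values are given for HFD-STZ vehicle against NCD vehicle (the model), HFD-STZ DHZ against HFD-STZ vehicle (the treatment) and HFD-STZ DHZ against NCD vehicle, in that order, with 9, 3796 and 2352 genes called, 14, 14 and 10 lists called, and 5 genes called in opposite directions by model and treatment. The model's count and the opposite count change by more than 1.5 times under most other settings, so their size rests on the procedure, and each group has only 3 libraries. The gene count of HFD-STZ DHZ against NCD vehicle changes that much under many, with 36 by library size only and 3981 with only the 2 groups compared. That of the treatment does so under some, with 888 by library size only. Over the alternatives, named genes that were called kept their label in 2500 values, lost the call in 667 and reversed in 0. Named genes that were not called reversed in 11 values.

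With library size only, 29, 888 and 36 genes were called (7 higher and 22 lower, 832 and 56, and 18 and 18), 18 lists in HFD-STZ DHZ against NCD vehicle, and 9 opposite genes. It turned 5 model estimates of genes not called: Cd44 −0.12, Cdh1 −0.40, Nfkbia −0.28, Cxcl10 −0.0845 and Ccng1 −0.26. With no filter the model gave 425 genes, HFD-STZ DHZ against NCD vehicle 20 lists, and the opposite count was 262. DESeq2 gave 126, 4707 and 3530 genes and 64 opposite. With limma-voom the model gave 2 genes and the opposite count was 1. With only the 2 groups compared, the model gave 3 genes and HFD-STZ DHZ against NCD vehicle 3981. With an estimated correlation 0, 0 and 0 lists were called, and with fry 1, 5 and 5.

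Alternatives chosen after the data were seen are these. A Y-linked library term gave 42, 3660 and 3617 genes and 23 opposite. Nuclear protein-coding genes only gave 7 treatment lists and 8 opposite genes. A GC and length offset gave 15 model genes and 8 opposite. Libraries without Y-linked transcripts only gave 137, 5766 and 4869 genes, 113 opposite, and 23 and 17 lists in the model and in HFD-STZ DHZ against NCD vehicle; Ehd3 lay at 0.0395 and Nqo1 at −0.0245 in the model, and mt-Nd2 at 0.0586 in the treatment. Libraries with Y-linked transcripts only gave 31, 159 and 79 genes; Cidec lay at 2.61 in the model and Lum at −0.0271 in HFD-STZ DHZ against NCD vehicle. A group is left with 1 library in every comparison of both subsets except HFD-STZ DHZ against NCD vehicle without Y-linked transcripts (2 against 2), and with them that comparison is 1 against 1; a lone library is assumed to vary like the others.

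Without NCD vehicle replicate 1, 2 or 3 the model gave 2, 2 and 2 genes, HFD-STZ DHZ against NCD vehicle 259, 779 and 1675, and the opposite count was 1, 1 and 1; Cidec in the model lay between −3.66 (without replicate 1) and 0.65 (without replicate 3). Without HFD-STZ vehicle replicate 1, 2 or 3 the model gave 28, 8 and 3 genes, the treatment 2831, 3486 and 3366, and the opposite count was 13, 6 and 2. The treatment gave 8 lists without replicate 2 and 16 without replicate 3. Left out in turn, HFD-STZ DHZ replicates 1, 2 and 3 left 1149, 1302 and 2952 genes in the treatment and 112, 245 and 1627 in HFD-STZ DHZ against NCD vehicle, and the opposite count was 4, 1 and 1. HFD-STZ DHZ against NCD vehicle gave 22 lists without HFD-STZ DHZ replicate 1.

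With the replicate number as a block, 2, 2159 and 772 genes were called and 1 opposite. The 9 pairs of libraries with the same number had correlations of −0.41 to 0.22 (median −0.18) against a median of 0.14 for other pairs, and only 3 exceeded 0.1. These values give no sign of pairing by number but cannot exclude it, since other differences between libraries enter them. The highest, 0.50, joined NCD vehicle replicate 1 and HFD-STZ DHZ replicate 3, both with Y-linked transcripts. The block costs residual degrees of freedom, and whether that alone lowers the counts was not tested.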

Other observations

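Among tubular injury genes, HFD-STZ DHZ replicate 3 held the highest value of all 9 libraries for 10 of the 14 tested. The list's call between HFD-STZ DHZ and NCD vehicle held whichever library was left out, with a median of 0.81 without this one in place of 1.54 (adjusted p = 0.0037, the highest of these fits). It was lost with an estimated correlation (adjusted p = 0.62 with an estimated correlation), and fry did not call the list (adjusted p = 0.068). Havcr1, which encodes the injury marker KIM-1 of the proximal tubule, stood there at 46.3 CPM against at most 2.59 in any other library. Lcn2 stood at 12.5 against 2.39 CPM, Vcam1 at 29.8 against 6.74, Spp1 at 1921 against 444, Cxcl1 at 15.7 against 3.51, the fibrinogen chain Fgb at 4.97 against 0.941 and Cd44 at 7.44 against 2.83. Sox9 was not among them, at 5.55 CPM in this library against up to 19.3 elsewhere.

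A term for libraries with Y-linked transcripts, chosen after the data were seen, gave 42 genes between HFD-STZ vehicle and NCD vehicle in place of 9. Among those added were transport and metabolic genes of the kidney: Slc16a6, a ketone body transporter (2.50, SE 0.25, adjusted p = 0.0014), Pck1 (2.26, SE 0.34, adjusted p = 0.025), Slc5a2 (−1.61, SE 0.25, adjusted p = 0.030), the fructose transporter Slc2a5 (−1.46, SE 0.23, adjusted p = 0.030) and Cyp27b1, which activates vitamin D (−4.56, SE 0.72, adjusted p = 0.030). Without the term their estimates were 2.77, 2.45, −1.62, −1.68 and −4.14, with adjusted p of 0.071, 0.052, 0.052, 0.14 and 0.19. Sox9 (3.82) and S100g (−2.99) had the smallest adjusted p with the term as without it.

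In this paragraph the test of the Y-linked library term was chosen only after the result was seen. Few genes, 9, were called between HFD-STZ vehicle and NCD vehicle, against 3796 after treatment. Mixing of libraries with and without Y-linked transcripts in each group is a candidate explanation for part of this, since the term raised the count to 42. With the term the treatment still gave 3660 genes, which argues against mixing as the source of the whole gap. The treatment comparison holds the same mixing and gave its 3796 genes without the term. A rise is not particular to the term, as 28 genes were called without HFD-STZ vehicle replicate 1. The Y-linked libraries of the 2 groups also had the higher mitochondrial shares (51.5%, 60.4% and 52.4% against 39.2% to 45.0%), so the term can take up RNA make-up too. Spread added by HFD-STZ vehicle replicate 2 stays open. Without this library 8 genes were called, from 1 library fewer, although the median SD of log2 CPM in the group fell to 0.598 of its value. A median SD over fewer libraries is lower by number alone, so part of this fall was given beforehand. No biological explanation was tested, and a mild effect of the model on these kidneys also stays open.

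Here the test of the spread between the HFD-STZ vehicle libraries was chosen only after the result was seen, and so was the reading of the simulated covariance. Fold changes of model and treatment ran in opposite directions, and the HFD-STZ vehicle libraries shared by both comparisons could give this in part. Their covariance minus the simulated mean was −0.171, and it lay under the lowest simulated value, which had been set beforehand as speaking against sharing alone; that bound was wrong, because the simulation gives all groups the same spread, while the mean variance of log2 CPM was 0.521 in HFD-STZ vehicle against 0.246 in NCD vehicle and 0.202 in HFD-STZ DHZ. Measured against the spread between the HFD-STZ vehicle libraries, the covariance was 1.57 times what that spread gives. HFD-STZ vehicle replicate 2 alone as the whole source goes poorly with a covariance of −0.256 without this library, beyond the simulated −0.202 to −0.155, but the correlation of −0.488 lay above the simulated −0.684 to −0.593, and a simulated bound excludes nothing here. A return of gene expression towards the healthy state under treatment therefore cannot be told apart from shared error of 3 libraries.

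Of the tests on this pattern, the GC and length offset was an alternative chosen only after the data were seen. Gene models of the class TEC, single-exon models that await experimental evidence, were lower in HFD-STZ DHZ than in HFD-STZ vehicle. Their median log2 fold change was −1.03 over 875 models (−1.13 to −0.93, bootstrap 95% interval) against 0.13 for protein-coding genes. With library size only it was −0.24 against 0.90. The intervals in this paragraph resample models, not libraries, so they leave out the spread between libraries. The fall was not limited to this class. Sense-intronic models had a median of −0.85 (3 called higher and 44 lower), processed transcripts −0.54, bidirectional promoter RNAs −0.47, processed pseudogenes −0.45 and antisense RNAs −0.44. Unprocessed pseudogenes had −0.10. The share of Malat1 was 4.55% ± 1.16 in HFD-STZ DHZ against 15.8% ± 6.80. For the TEC models, GC content or gene length bias is argued against by a median of −1.003 (−1.08 to −0.88) with the offset. A difference in depth is argued against by −1.35 (−1.46 to −1.23) over the 495 TEC models that passed the filter again after thinning. That filter can favour models that are high in the other groups. The median of these 495 before thinning was not computed, so −1.35 and −1.03 cover unlike sets. Carry-over of unspliced precursor RNA could explain part of it and stays open. TEC models inside a coding gene on its strand had a median of −1.16 (−1.26 to −1.03) and intergenic ones −0.84 (−1.16 to −0.38). Their difference was −0.33, and its interval of −0.74 to 0.04 includes 0. Those on the other strand of a coding gene had −0.54 (−1.16 to −0.19) and those near or partly in one −0.26 (−0.76 to 0.002). Precursors of the coding genes in the annotation would not by themselves lower the intergenic models. Each library of HFD-STZ DHZ had a lower mean log2 CPM of these models (−0.48, −0.63 and −0.24) than any other library (−0.01 to 0.38), and the batch dates, which follow the groups, cannot be told apart from the treatment.

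Other splits of the 6 libraries of a comparison are too few, at 10, for a share under 0.05. For HFD-STZ vehicle against NCD vehicle, 2 of the 10 splits gave as many genes (9, highest other 14) and 3 as many lists (14, highest other 18). The split with 14 genes and 18 lists sets the Xist-expressing libraries against the Y-linked ones. These also differ in mitochondrial share (41.5%, 39.2% and 45.0% against 51.5%, 60.4% and 52.4%), so sex and RNA make-up cannot be told apart. Camera called the mitochondrial genome lower in the Xist-expressing ones (adjusted p = 3.8e-22). It called the podocyte, endothelial, white adipocyte and ribosome lists higher, all of them the reverse of the model's calls. Macrophage, antigen presentation and glycolysis lists were higher as after treatment, and the NRF2 list lower, unlike after treatment. In a check made after this was seen, none of these 14 genes was Xist or another sex chromosome check gene, and all 14 lie on autosomes. That absence says little, because the fit keeps the HFD-STZ DHZ group. This group mixes both kinds of library, so the spread of the check genes in it counts against a call. In the same check camera called male-biased kidney genes lower (adjusted p = 8.4e-17) and female-biased ones higher (adjusted p = 1.6e-04) in the Xist-expressing libraries. For HFD-STZ DHZ against HFD-STZ vehicle, 1 split, the real one, gave as many genes (3796, highest other 0) and 6 as many lists (14, highest other 22). In HFD-STZ DHZ against NCD vehicle, 1 split gave as many genes (2352, highest other 0) and 8 as many lists (10, highest other 26). Of 50 drawn splits of all 9 libraries, 3 gave as many opposite genes as the real 5, the real split among them, and the highest other gave 1610. That split has the 3 HFD-STZ DHZ libraries as the shared group, so it carries the difference of this group from all others and is no draw without effects. With it the share is not under 0.05, and without it, at 2 of 49, it is. The 45 splits that divide the HFD-STZ DHZ libraries gave 0. In a test chosen after this result was seen, the HFD-STZ DHZ group was kept and the other 6 libraries were split in all 20 ways, too few for a share under 0.05. Of these, 4 gave as many as the real 5, and the highest other gave 9, in a split of Xist-expressing against Y-linked libraries. The same split with the other part shared gave 8, and the real grouping with NCD vehicle shared gave 6. All other splits gave 0. These splits therefore do not settle whether chance can be excluded.

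Trim30a and its family members Trim30c, Trim12c, Trim30b and Trim34a stood far higher in HFD-STZ vehicle replicate 2 than in any other library, at 8901, 1761, 2792, 981 and 251 CPM against at most 1299.7, 261, 384, 149 and 47.5. The same library had the highest mitochondrial share of all 9 (60.4%).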
